A study of Homo sapiens with 18 samples.

How the data were processed

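Gene expression was measured on 18 single-colour Affymetrix arrays, 3 for each of days 0, 1, 3, 7, 14 and 21 after human neural progenitor cells were moved to differentiation medium. Per the labels, the cells came from WA09 embryonic stem cells and the 3 replicates of each day came from separate cell preparations. RNA was labelled with biotin as single-stranded DNA, per the labels. The submitters' processing notes name limma, without a version or a role. The deposited value table was used as the authors processed it, and its unit was read as log2 of intensity: the values run from 2.20 to 14.69, and no label states the log base. Background correction, summarization and normalization are not given in the sources used here. Array medians over all rows lay between 7.69 and 7.80, and the lower and upper quartiles differed between arrays by at most 0.15 and 0.12, so the columns were taken as already normalized between arrays. The rule fixed beforehand called for quantile normalization unless the columns shared 1 distribution, so leaving it out was a judgement made on these values. Quantile normalization is given as an alternative. All fold changes below assume log2 values. No scanner files were analysed here, so signal over background was not measured, and the number of arrays limits the precision.

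The value table has 33297 rows. The platform's name table gave 1 gene symbol for 19460 rows, several for 1754, and did not list 12083. Of the rows with 1 gene, 19429 matched the reference gene table by Entrez identifier and 0 symbols were updated. Rows with several genes or none were left out. Where several rows named a gene (769 genes), the row with the highest mean over the 18 arrays stood for it, which left 18417 genes. Rows of a gene that were each called in opposite directions occurred in at most 6 genes per comparison with day 0. No filter on dim genes was applied.

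Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with a mean per day over all 18 arrays, 12 residual degrees of freedom and 3.76 prior degrees of freedom. The 9 comparisons were each later day against day 0 and each step between neighbouring days, with Benjamini-Hochberg adjustment over all genes within each comparison and a threshold of 0.05. A moderated F test over the 5 comparisons with day 0 asked whether a gene changed on any day. Genes called by it with a range of day means of at least 1 on the log2 scale were counted by the day of their highest and lowest mean. All adjusted p-values of single genes come from this limma fit. Values are given as mean ± SD of the log2 level over n = 3 arrays.

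The 34 gene lists were written from textbook knowledge. They cover neural progenitors, mitosis, DNA replication, proneural transcription factors, neuronal cytoskeleton, axon guidance, synapse, glutamate, GABA, monoamine and acetylcholine genes, voltage-gated channels, astrocytes, radial glia, oligodendrocytes, pluripotency, neural crest, mesenchyme and smooth muscle, endothelium, epithelium, macrophages, forebrain and HOX factors. They also cover the Notch, Wnt, Hedgehog, BMP and FGF pathways, immediate early genes, cholesterol synthesis, hypoxia and glycolysis, p53 targets, the unfolded protein response with ATF4 targets, interferon response and housekeeping genes. Each list was tested against all other genes with camera in limma, two-sided, with a preset inter-gene correlation of 0.01. The 170 tests, 34 lists on 5 days against day 0, were adjusted together. The same test with a correlation estimated per list was an alternative. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone.

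The genes named in the text follow a rule: for each day against day 0, the 10 largest rises and 10 largest falls among called genes whose 3 arrays all lay on the same side of the 3 day 0 arrays. For each step between neighbouring days the rule takes 5 of each, and for each list up to 4 called members with the largest change. The text names fewer, from the top down. Uncharacterised genes, small RNAs, antisense transcripts, pseudogenes and genes specific to a sex chromosome were left out of the rule. Groups, comparisons, tests, lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

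The labels number the replicates 1 to 3 on every day, without saying that a number marks a shared preparation. Deviations from the day means were therefore correlated between arrays of the same number, across genes, and a comparison was taken as paired where all 3 correlations exceeded 0.1. This held for 3 of the 9 comparisons. The correlations for replicates 1, 2 and 3 were 0.26, 0.35 and 0.32 for day 3 against day 0, 0.14, 0.22 and 0.54 for day 7 against day 3, and 0.34, 0.58 and 0.55 for day 21 against day 14. For these the fit with the number as a replicate block is given beside a result where it changes a call or moves a count by more than 1.5 times. Across different days the mean correlation was 0.154 for arrays of the same number and -0.077 for arrays of other numbers. By this measure 13 arrays lay closest to their own number. A shared preparation may therefore reach beyond the 3 comparisons, and the reported fit, which has no block, does not model it.

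The alternatives were the replicate block, the replicate number as a random effect, fits of only the 6 arrays compared, quantile normalization applied again, centring on array medians, leaving out genes below the median level, averaging the rows of a gene, testing each row, a trended robust prior, array weights, leaving out each array in turn, fry in place of camera and the estimated correlation. Another 4 settings were added after the data were examined: removing the trend with genomic gene length from each array, the same with the replicate block, leaving out all day 1 arrays, and applying the centring to the list tests. Genomic length was known for 18392 of the 18417 genes (99.86%).

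The fit was tested on simulated data before use. With known changes added to unchanged arrays of the same size, for day 21 against day 0 and all 18417 genes, 41.8% of genes with a change of 0.5 (log2) were recovered, 86.6% with a change of 1 and 98.5% with a change of 2. Of 169 calls, 8 were false (4.73%). With no change, at most 1 gene was called in any of the 9 comparisons. The simulated noise was independent between genes and had the same spread on all days, and few genes were changed. The real arrays hold correlated genes, unequal spread between days and many more calls, so these rates may not carry over to them.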

Results

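Gene expression was followed for 21 days in cultures of human neural progenitor cells, which divide and can form neurons and glia. The cells were derived from WA09, an established human embryonic stem cell line, and differentiation was started by moving attached cells to a neuronal medium without growth factor. Arrays were made on days 0, 1, 3, 7, 14 and 21, with 3 arrays per day from separate cell preparations, and 18417 genes were tested. Day 0 served as the reference, and the question of the series is how expression changes over time once differentiation has begun. The deposited values were read as log2 intensities, with array medians between 7.69 and 7.80 over all rows.

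Of the 18417 genes, 10216 (55.5%) changed over time in limma's moderated F test. Among these, 3135 had day means that differed by at least 1 on the log2 scale. Their lowest mean fell on day 0 for 1613 genes and on day 1 for 553. Their highest mean fell on day 3 for 922 genes, on day 21 for 871 and on day 1 for 688. The first principal component held 35.3% of the variance and parted day 0 (scores -60.42 to -44.04) from all later arrays (-11.37 to 34.26). The second held 33.2% and ran from day 1 (-45.18 to -23.76) to day 21 (32.76 to 48.09). The 3 day 1 arrays lay far apart on the first component, and the lowest correlation between arrays of a day was 0.973 on day 1 and 0.983 on day 21, against 0.993 on day 0.

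**Figure D1:**
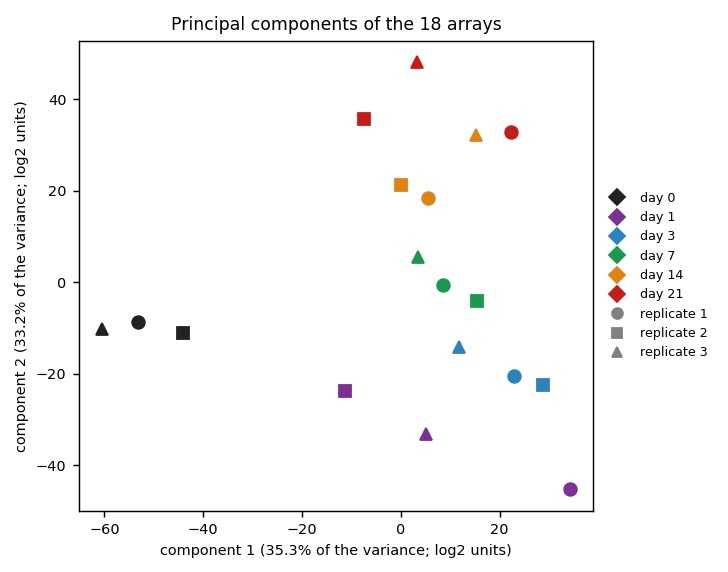
Principal components 1 and 2 of the 18 arrays (log2 units), coloured by day, with a symbol per replicate. Day 0 arrays lie at -60.42 to -44.04 on component 1, and day 21 arrays at 32.76 to 48.09 on component 2.

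The comparison of day 1 with day 0 asks which genes respond first once differentiation starts. ID1, a transcriptional target of BMP signalling, rose 20.7-fold in 1 day, from 8.38 ± 0.22 to 12.75 ± 0.26 (mean ± SD of log2, n = 3, adjusted p = 4.38e-10). ID1 was read from row 8061564 of the value table, on chromosome 20. GASK1B rose 17.1-fold, DOK5, an adaptor of receptor tyrosine kinases, 15-fold and LGI2 12.8-fold, each in 3 of 3 arrays, as the naming rule requires. EGR1, an immediate early gene downstream of ERK, fell most, from 12.10 ± 0.30 to 9.43 ± 0.52, or 6.35-fold lower (n = 3, adjusted p = 9.55e-05). ICAM1, a cell adhesion molecule, was 6.11-fold lower and TXNIP, which binds thioredoxin and restrains glucose uptake, 5.68-fold lower.

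Of the 16 measured BMP pathway genes, 9 rose and 1 fell on day 1 (9 and 2 adjusted over the list alone), with a median log2 change of 0.92. The members that rose include antagonists as well as targets: GREM1, which binds and blocks BMPs, was 9.79-fold higher and the pseudoreceptor BAMBI 4.21-fold higher. The list was higher than other genes (camera adjusted p = 4.89e-06, adjusted p = 0.207 with an estimated correlation). Of 14 measured cholesterol synthesis genes, 11 fell and 0 rose (13 and 1 adjusted over the list alone), with a median of -1.25. Among them LSS, which closes the sterol ring, fell from 11.15 ± 0.05 to 9.46 ± 0.54 and DHCR7, the last enzyme of the pathway, from 12.45 ± 0.07 to 10.47 ± 1.08 (n = 3). The camera adjusted p was 0.00028, and the adjusted p = 0.696 with an estimated correlation. The mean change of this list in day 1 replicates 1, 2 and 3 was -1.55, -0.46 and -1.42. Mitosis genes had begun to rise, 14 of 22 (14 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 3.41e-08, adjusted p = 0.394 with an estimated correlation). Their mean change in day 1 replicates 1, 2 and 3 was 0.98, 0.51 and 0.96. Of 27 axon guidance genes, 11 rose and 2 fell (12 and 4 adjusted over the list alone), led by the secreted guidance cue SEMA3C, 7.26 ± 0.02 to 10.16 ± 0.53. For these the camera adjusted p was 0.00718, the adjusted p = 0.389 with an estimated correlation and 0.117 once the gene-length trend was removed. Of 16 immediate early genes, 8 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.0481, adjusted p = 0.632 with an estimated correlation). That call was lost without day 0 replicate 2 (adjusted p = 0.0632), day 0 replicate 3 (0.0549), day 1 replicate 2 (0.136) or day 1 replicate 3 (0.0533), with array medians centred (0.0817) and with dim genes left out (0.0797).

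In all, 6371 genes changed between days 0 and 1, 2944 higher and 3427 lower, of which 1200 were at least 2-fold higher and 225 at least 2-fold lower. Without day 1 replicate 1 the count was 3957. After removal of the gene-length trend 3233 genes were higher and 2215 lower, so that 59.3% of the calls were higher against 46.2%. With array medians centred 2750 were higher and 4689 lower (37%).

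**Figure D2:**
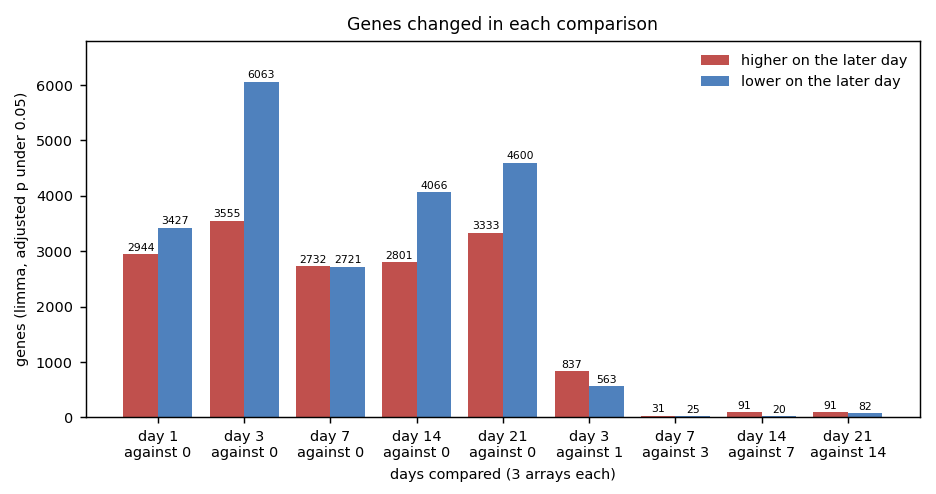
Genes higher (red) and lower (blue) on the later day in each of the 9 comparisons at an adjusted p under 0.05 in limma, with counts above the bars. Comparisons with day 0 gave 5453 to 9618 genes, and steps after day 3 gave 56 to 173.

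Day 3 against day 0 asks what has changed in the first days. CYP26A1, the enzyme that degrades retinoic acid, had risen 28.7-fold, from 7.18 ± 0.43 to 12.02 ± 0.10 (n = 3, adjusted p = 2.88e-07, row 7929322, chromosome 10). GASK1B was 23.9-fold, DOK5 22.9-fold and ID1 19.8-fold higher. ETV4, a transcription factor induced by FGF signalling, fell from 11.59 ± 0.17 to 8.15 ± 0.41, or 10.9-fold lower (n = 3, adjusted p = 8.15e-08). HAS2, a hyaluronan synthase, was 8.78-fold lower and TXNIP 8.72-fold lower.

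All 22 mitosis genes rose by day 3 (22 and 0 adjusted over the list alone), with a median log2 change of 1.22. DLGAP5, a spindle protein, rose from 7.04 ± 0.34 to 10.27 ± 0.33 and the motor protein KIF11 from 7.44 ± 0.16 to 9.99 ± 0.28. TOP2A, which untangles DNA before division, rose from 7.95 ± 0.30 to 10.43 ± 0.26 (n = 3 each). The camera adjusted p was 7.6e-16, with an adjusted p = 0.176 with an estimated correlation. Of the 22 DNA replication genes, 7 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.00318, adjusted p = 0.731 with an estimated correlation, 0.0678 with dim genes left out). Their largest rise was that of POLA1, a polymerase subunit, from 7.62 ± 0.13 to 9.17 ± 0.18. Of 16 p53 targets, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.0257, adjusted p = 0.731 with an estimated correlation). They include ZMAT3, 3.57-fold higher, and MDM2, the ligase that degrades p53, 2.23-fold higher. CDKN1A, the p53-induced inhibitor of the cell cycle, was at 11.06 ± 0.26 against 11.14 ± 0.44 (adjusted p = 0.783), as read after the data were examined. The p53 call was lost without day 0 replicate 2 (adjusted p = 0.0605), day 0 replicate 3 (0.058) or day 3 replicate 1 (0.059), after quantile normalization was applied again (0.0576) and with dim genes left out (0.269).

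Feedback genes of FGF and ERK signalling fell: 14 of 18 members were lower and 0 higher on day 3 (15 and 0 adjusted over the list alone), with a median of -0.89. DUSP6, the ERK phosphatase, fell from 12.69 ± 0.14 to 9.64 ± 0.36 and ETV5 from 10.74 ± 0.11 to 8.53 ± 0.55 (n = 3). The camera adjusted p was 0.00029, with an adjusted p = 0.482 with an estimated correlation. The list was also called on days 7, 14 and 21 (adjusted p = 1.54e-05, 0.000689 and 0.0107), with adjusted p = 0.399, 0.541 and 0.696 with an estimated correlation. Of 19 hypoxia and glycolysis genes, 12 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.45. The glucose transporters SLC2A1 and SLC2A3 were 3.72-fold and 2.99-fold lower (camera adjusted p = 0.00227, adjusted p = 0.394 with an estimated correlation). Cholesterol synthesis genes were lower in 11 members and higher in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0305, adjusted p = 0.796 with an estimated correlation). The mean change of this list in day 3 replicates 1, 2 and 3 was -1.02, -0.48 and -0.96. With the replicate block the camera adjusted p of the cholesterol list was 0.0535. Without day 3 replicate 1 or replicate 3 it was 0.0502 and 0.0602, and with array medians centred 0.0615. The 16 BMP pathway genes held 11 higher and 3 lower members (11 and 4 adjusted over the list alone), with a median of 1.75 (camera adjusted p = 6.38e-07, adjusted p = 0.176 with an estimated correlation).

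Between days 0 and 3, 9618 genes changed, 3555 higher and 6063 lower, with 1382 at least 2-fold higher and 210 at least 2-fold lower. Genes of greater genomic length tended to have more positive changes. Over the 9206 brighter genes Spearman's rho of length with the signed log2 change was 0.36, with a median change of -0.24 in the shortest 10% and 0.36 in the longest 10%. That correlation is across genes, which are not independent replicates, and it was 0.29 to 0.33 on the other days against day 0. With the length trend removed, 4005 genes were higher and 3268 lower (55.1% higher against 37%), with dim genes left out 2467 and 2620 (48.5%), and with array medians centred 3226 and 8478 (27.6%).

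The step from day 1 to day 3 asks how the early response proceeds. ACTA2, smooth muscle actin, rose 8.26-fold, from 9.36 ± 0.27 to 12.41 ± 0.57 (n = 3, adjusted p = 1.59e-05). CYP26A1 rose 6.91-fold in this step and LIX1 6.79-fold. SPP1, the secreted protein osteopontin, fell from 12.80 ± 0.44 to 9.16 ± 0.44, or 12.5-fold lower (n = 3, adjusted p = 0.000276). NT5E, which makes adenosine outside the cell, was 11.6-fold lower and the neuropeptide gene GAL 7.85-fold lower. In this step 1400 genes changed, 837 higher and 563 lower, and the count was 920 without day 3 replicate 1 and 871 without day 3 replicate 3. Array weights gave 3004 higher and 3292 lower (47.7% higher against 59.8%), and the fit of these 6 arrays alone gave 600 genes.

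**Figure D3:**
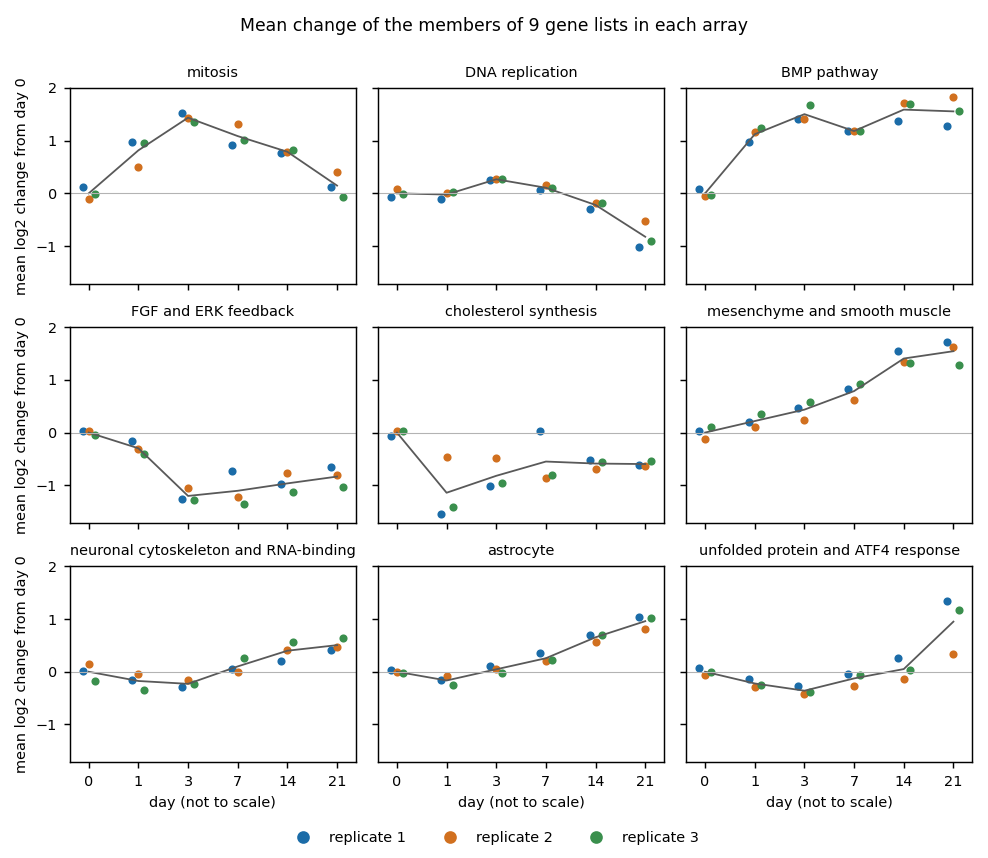
Mean log2 change from day 0 of the members of 9 gene lists in each array, coloured by replicate, with a line through the means of 3 arrays. The mitosis list was highest on day 3, and the unfolded protein list stood at 1.33, 0.34 and 1.18 in day 21 replicates 1, 2 and 3.

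Day 7 against day 0 addresses the state after a week of differentiation. CYP26A1 was 38.4-fold higher than on day 0, at 12.44 ± 0.12 (n = 3, adjusted p = 1.48e-07), and PI15, a peptidase inhibitor, 20.9-fold higher. DOK5 was 17.1-fold, the growth factor TGFB2 15.4-fold and ACTA2 13-fold higher. TXNIP was 12-fold lower, DUSP6 10.9-fold lower and the neuropeptide gene NMU 9.27-fold lower. CALB1, a calcium-binding protein of some neurons, fell from 13.04 ± 0.04 to 9.91 ± 0.26 (n = 3, adjusted p = 6.38e-07).

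Of 21 measured Wnt pathway genes, 7 rose and 1 fell on day 7 (10 and 2 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.00788, adjusted p = 0.176 with an estimated correlation). LGR5, the receptor for R-spondins, rose from 6.15 ± 0.14 to 8.70 ± 0.64 and WNT5A from 7.90 ± 0.21 to 9.95 ± 0.30 (n = 3). DKK1, a secreted Wnt inhibitor, was 5-fold higher. On days 14 and 21, 11 members were higher and 2 lower (11 and 4 adjusted over the list alone on each), with camera adjusted p = 0.00122 and 0.00433 and adjusted p = 0.176 on both with an estimated correlation. With dim genes left out the Wnt list was not called on day 7 (adjusted p = 0.0853) or day 21 (0.0531). AXIN2, a target of the pathway, was 4.17-fold higher on day 14 and 4.01-fold higher on day 21.

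Of 21 neural progenitor genes, 7 rose and 3 fell on day 7 (8 and 3 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0189, adjusted p = 0.399 with an estimated correlation). The call was lost without day 7 replicate 3 (adjusted p = 0.0521) and with dim genes left out (0.0797). ZIC1 and DACH1, transcription factors of the early neural tube and eye field, rose from 10.02 ± 0.03 to 11.97 ± 0.34 and from 7.65 ± 0.42 to 9.59 ± 0.17, while LIN28A, an RNA-binding protein of early progenitors, fell from 11.50 ± 0.32 to 9.77 ± 0.18 (n = 3). Of 25 synapse genes, 7 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.0333, adjusted p = 0.66 with an estimated correlation, 0.0589 with array medians centred, 0.0868 with dim genes left out). UNC13A, which primes synaptic vesicles, was at 7.36 ± 0.15 against 9.25 ± 0.04. Mitosis genes stood higher in 19 of 22 members (20 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 7.08e-14, adjusted p = 0.176 with an estimated correlation).

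Day 7 differed from day 0 in 5453 genes, 2732 higher and 2721 lower, or in 3244 without day 0 replicate 3 and 3461 without day 7 replicate 2. With array medians centred, 2392 genes were higher and 5331 lower, which is 31% higher against 50.1%. With the length trend removed 2897 were higher and 2121 lower (57.7%). Quantile normalization applied again gave 2670 higher and 3802 lower (41.3%), and array weights 4154 and 6094 (40.5%).

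The step from day 3 to day 7 asks what changes between those days. SFRP4, a secreted Wnt modulator, rose from 5.80 ± 0.20 to 8.74 ± 0.08, or 7.69-fold (n = 3, adjusted p = 0.00229). IGFBP3, which binds insulin-like growth factors, rose 4.55-fold and CEMIP, which degrades hyaluronan, 3.58-fold. Only 56 genes changed, 31 higher and 25 lower, with 1879 at an unadjusted p under 0.05, and with the replicate block 158 changed. The count fell to between 17 and 33 without each of the 6 arrays in turn (30, 17 and 33 without day 3 replicates 1, 2 and 3, and 23, 26 and 22 without those of day 7). The share higher was 66.7% to 86.4% in these fits. With all day 1 arrays left out 44 genes were higher and 56 lower, 100 in total. With the length trend removed, 29 genes were higher and 45 lower (39.2% higher against 55.4%).

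Day 14 against day 0 addresses later differentiation. The largest rises were those of CYP26A1, 40.2-fold, and SFRP4, 34.2-fold, from 5.42 ± 0.04 to 10.52 ± 0.79 (n = 3, adjusted p = 1.93e-07). CALB2, the calcium-binding protein calretinin, rose 27.6-fold. TXNIP was 23-fold lower, at 8.16 ± 0.89 against 12.68 ± 0.06 (n = 3, adjusted p = 3.94e-06), ETV4 8.45-fold lower and LIN28A 8.1-fold lower.

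Mesenchyme and smooth muscle genes rose on day 14 in 14 of 21 members and fell in 1 (15 and 1 adjusted over the list alone), with a median log2 change of 1.38. ACTA2 rose from 9.55 ± 0.74 to 13.44 ± 0.17, LUM, a collagen-binding proteoglycan, from 6.59 ± 0.58 to 10.33 ± 0.14, and COL3A1 from 8.16 ± 0.20 to 11.81 ± 0.45 (n = 3). The member that fell was THY1, a surface protein of fibroblasts and of neurons, at 7.63 ± 0.07 against 9.96 ± 0.23, named after its values were seen. The camera adjusted p was 6.95e-09, with an adjusted p = 0.176 with an estimated correlation. The list was also called on day 3 (8 higher, 3 lower, the same adjusted over the list alone; adjusted p = 0.0423, adjusted p = 0.731 with an estimated correlation) and on day 7 (9 and 1, or 10 and 1 adjusted over the list alone; adjusted p = 0.000286, adjusted p = 0.451 with an estimated correlation). The day 3 call was lost without day 0 replicate 2 (0.093) or day 3 replicate 3 (0.0881), with the length trend removed (0.122), after quantile normalization was applied again (0.0802) and with dim genes left out (0.154).

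Of 21 astrocyte genes, 9 rose and 4 fell on day 14 (10 and 5 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.0205, adjusted p = 0.264 with an estimated correlation). NFIA, a transcription factor that switches progenitors toward glia, rose from 5.93 ± 0.16 to 9.68 ± 0.63 and the gap junction gene GJA1 from 9.27 ± 0.20 to 11.85 ± 0.37 (n = 3). Of 23 neuronal cytoskeleton genes, 10 rose and 4 fell (11 and 4 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.036, adjusted p = 0.599 with an estimated correlation). MAP1B, a microtubule-binding protein, rose from 11.22 ± 0.22 to 12.90 ± 0.07 and the adhesion gene L1CAM fell to 8.05 ± 0.22 from 9.96 ± 0.22. The cytoskeleton call was lost without day 0 replicate 3 (adjusted p = 0.0612) or day 14 replicate 3 (0.0764), with the length trend removed (0.161) and with dim genes left out (0.0846). BMP pathway genes were higher in 12 members and lower in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 6.95e-09, adjusted p = 0.176 with an estimated correlation). Mitosis genes were still higher in 14 of 22 (14 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 3.34e-08, adjusted p = 0.394 with an estimated correlation).

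Day 14 differed from day 0 in 6867 genes, 2801 higher and 4066 lower, or in 4513 without day 0 replicate 1, 3861 without day 0 replicate 3 and 3978 without day 14 replicate 3. The share of calls that were higher was 40.8%, against 26% (2391 higher, 6809 lower) with array medians centred and 57.1% (3152 higher, 2365 lower) with the length trend removed.

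The step from day 7 to day 14 asks which genes join in the following week. DCN, the proteoglycan decorin, rose from 5.36 ± 0.56 to 8.11 ± 0.44, or 6.76-fold (n = 3, adjusted p = 0.000451). TAC1, which encodes substance P, rose 5.42-fold and NFIA 5.28-fold. SALL4, a transcription factor of stem cells, fell from 10.52 ± 0.04 to 9.33 ± 0.37 (n = 3, adjusted p = 0.0027). In this step 111 genes changed, 91 higher and 20 lower (82% higher), or 75 and 33 with dim genes left out (69.4%) and 553 and 701 with array weights (44.1%). The count was 56, 21 and 58 without day 7 replicates 1, 2 and 3, and 66 and 62 without day 14 replicates 2 and 3.

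**Figure D4:**
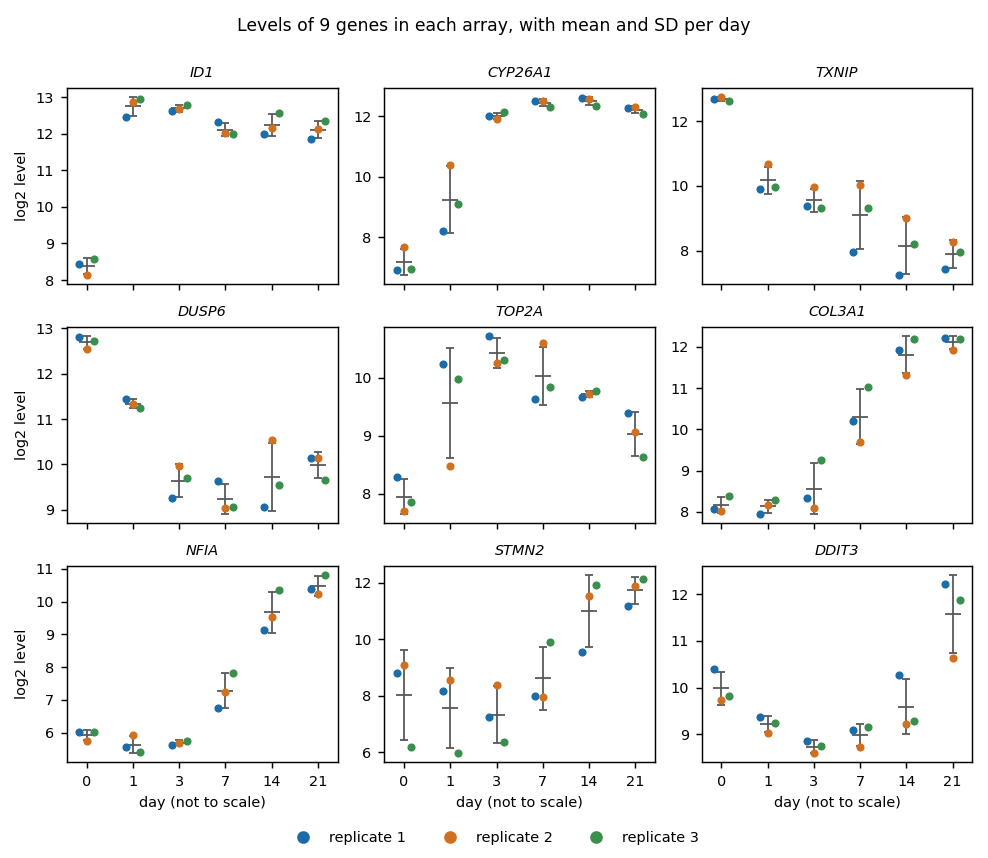
Log2 levels of 9 genes in each array by day, coloured by replicate, with the mean and SD of 3 arrays in grey. DDIT3 stood at 12.23, 10.64 and 11.87 in day 21 replicates 1, 2 and 3, and STMN2 at 8.79, 9.07 and 6.18 in those of day 0.

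Day 21 against day 0 compares the end of the series with its start. SFRP4 had risen 68.5-fold over day 0, to 11.52 ± 0.94 from 5.42 ± 0.04 (n = 3, adjusted p = 3.04e-08, row 8139087, chromosome 7). RSPO3, a secreted Wnt agonist, was 34.7-fold higher, CYP26A1 32.9-fold, CALB2 27-fold and NFIA 23.4-fold. TXNIP fell most, from 12.68 ± 0.06 to 7.89 ± 0.43, or 27.8-fold lower (n = 3, adjusted p = 1.41e-06, row 7904726, chromosome 1). LIN28A was 12.4-fold lower and APOBEC3B, a cytidine deaminase, 9.66-fold lower.

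Of 22 DNA replication genes, 21 fell and 0 rose by day 21 (21 and 0 adjusted over the list alone), with a median of -0.87. RRM2, a subunit of ribonucleotide reductase, fell from 11.44 ± 0.10 to 9.72 ± 0.14 and the helicase factor CDC45 from 10.81 ± 0.10 to 9.54 ± 0.37 (n = 3). The mean change of the list in day 21 replicates 1, 2 and 3 was -1.02, -0.53 and -0.91. The camera adjusted p was 6.95e-09, with an adjusted p = 0.399 with an estimated correlation. Mitosis genes went both ways, with 5 higher and 6 lower (6 and 7 adjusted over the list alone) and a median of 0.11 (camera adjusted p = 0.513): DLGAP5 stood at 8.32 ± 0.42 against 7.04 ± 0.34 and AURKB, a kinase of chromosome segregation, at 10.56 ± 0.45 against 11.40 ± 0.11. Of 15 measured pluripotency genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.00433, adjusted p = 0.429 with an estimated correlation). LIN28A, SALL4 and GAL led them, and POU5F1 and NANOG were the 2 members with no row of their own. That list was also called on day 14 (adjusted p = 0.00416, adjusted p = 0.429 with an estimated correlation) and day 7 (adjusted p = 0.0335, adjusted p = 0.602 with an estimated correlation). The day 7 call was lost without day 0 replicate 3 (0.0549) or day 7 replicate 1 (0.0522), after quantile normalization was applied again (0.0679) and with the length trend removed (0.0566).

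Several neural and glial lists were higher on day 21. The synapse list was not called on day 14 or 21 (medians -0.075 and -0.042, camera adjusted p = 0.718 and 0.836). Of the 27 axon guidance genes, 15 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 6.7e-07, adjusted p = 0.176 with an estimated correlation). DCC, a netrin receptor, rose from 8.40 ± 0.31 to 11.42 ± 0.44 (n = 3). The list was called on day 14 as well (adjusted p = 6.1e-05, adjusted p = 0.176 with an estimated correlation) and on day 7 (adjusted p = 0.0217, adjusted p = 0.429 with an estimated correlation, 0.213 with the length trend removed, 0.107 with dim genes left out). Of 23 neuronal cytoskeleton genes, 11 rose and 5 fell (12 and 5 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.0349, adjusted p = 0.599 with an estimated correlation). STMN2, a microtubule regulator of growing axons, rose from 8.01 ± 1.60 to 11.72 ± 0.49 and DCX, a marker of migrating young neurons, from 7.36 ± 0.37 to 9.12 ± 0.51. This call was lost without day 0 replicate 3 (adjusted p = 0.0549) or day 21 replicate 3 (0.0717), with the length trend removed (0.159) and with dim genes left out (0.125). Of 21 astrocyte genes, 10 rose and 3 fell (12 and 5 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.000685, adjusted p = 0.176 with an estimated correlation). SPARCL1 rose from 6.28 ± 0.09 to 9.12 ± 0.88, whereas GFAP, the astrocyte filament gene, was at 8.14 ± 0.03 against 8.40 ± 0.11 (adjusted p = 0.0517), as read after the data were examined. Mesenchyme genes were higher in 16 of 21 and lower in 1 (16 and 1 adjusted over the list alone), with a median of 1.59 (camera adjusted p = 1.52e-08, adjusted p = 0.186 with an estimated correlation), and BMP genes in 12 of 16 and 1 (12 and 1 adjusted over the list alone; camera adjusted p = 4.88e-08, adjusted p = 0.176 with an estimated correlation).

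The unfolded protein and ATF4 response rose on day 21 in 14 of 18 members, with 0 lower (15 and 0 adjusted over the list alone), and a median of 0.77. SLC7A11, the cystine transporter, rose from 7.99 ± 0.16 to 10.47 ± 0.95 and DDIT3, the stress factor CHOP, from 9.99 ± 0.36 to 11.58 ± 0.83 (n = 3). For this list the camera adjusted p was 3.86e-07, with an adjusted p = 0.521 with an estimated correlation. Day 21 replicate 2 stood apart in this list: its mean change was 0.34, against 1.33 and 1.18 in replicates 1 and 3.

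Day 21 differed from day 0 in 7933 genes, 3333 higher and 4600 lower, with 1018 at least 2-fold higher and 329 at least 2-fold lower. Centring on array medians shifted the median change of all genes by -0.107 and gave 2713 higher and 7706 lower (26% higher against 42%), and removal of the length trend gave 3746 and 2959 (55.9%).

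The step from day 14 to day 21 asks what changes in the last week. FBLN5, an elastic fibre protein, rose from 9.62 ± 0.45 to 11.57 ± 0.64, or 3.86-fold (n = 3, adjusted p = 0.00186), and FAIM2, an inhibitor of Fas-driven cell death in neurons, rose 3.41-fold. DDIT3 rose 3.97-fold, from 9.59 ± 0.59 (adjusted p = 0.0112), a call that was lost without day 14 replicate 2 (adjusted p = 0.0751), day 21 replicate 1 (0.0531) or day 21 replicate 3 (0.081). RRM2 fell from 10.70 ± 0.09 to 9.72 ± 0.14 (n = 3, adjusted p = 8.95e-05). Between days 14 and 21, 173 genes changed, 91 higher and 82 lower, and 328 with the replicate block. The fit of these 6 arrays alone called 0 genes, and array weights 2158. Quantile normalization applied again gave 72 higher and 43 lower (62.6% higher against 52.6%), and leaving out dim genes gave 45 higher and 140 lower (24.3% higher). Centring gave 81 higher and 98 lower (45.3%), and removal of the length trend 101 and 136 (42.6%). The count was 773 without day 21 replicate 2, and 79, 20 and 96 without day 14 replicates 1, 2 and 3, and 55 and 26 without day 21 replicates 1 and 3. The share higher ran from 51.9% without day 21 replicate 2 to 95% without day 14 replicate 2, and was 45.5% with all day 1 arrays left out.

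Hypoxia genes were also lower on the later days. Of 19 hypoxia and glycolysis genes, 12, 11 and 11 were lower on days 7, 14 and 21, and 0, 0 and 2 higher (13, 11 and 12 lower and 0, 0 and 2 higher adjusted over the list alone). ADM, the hypoxia-induced peptide adrenomedullin, was at 9.56 ± 0.50, 9.02 ± 0.33 and 9.16 ± 0.14 on those days against 11.76 ± 0.15 (n = 3). In camera, the adjusted p was 0.00029, 0.00498 and 0.0134, with adjusted p = 0.264, 0.421 and 0.468 with an estimated correlation, and without day 21 replicate 2 the day 21 value was 0.0562. On FGF and ERK feedback, 1, 1 and 3 members were higher and 12, 12 and 11 lower on days 7, 14 and 21 (1, 1 and 3 higher and 13, 13 and 12 lower adjusted over the list alone). Cholesterol synthesis genes were lower in 5 and higher in 0 members on day 7 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0426, adjusted p = 0.806 with an estimated correlation). That call was lost without day 0 replicate 2 (0.0808), day 7 replicate 2 (0.127) or day 7 replicate 3 (0.132), after quantile normalization was applied again (0.0802) and with array medians centred (0.115). The mean change of the list in day 7 replicates 1, 2 and 3 was 0.02, -0.86 and -0.81. Immediate early genes were lower in 9 and higher in 1 of 16 on day 3 (10 and 1 adjusted over the list alone), with FOS, a subunit of AP-1, at 8.38 ± 0.25 against 9.66 ± 0.09 (n = 3). By camera the adjusted p was 0.036, the adjusted p = 0.599 with an estimated correlation, 0.0505 with the replicate block, 0.0504 without day 3 replicate 2 and 0.0597 with array medians centred.

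Some markers of other lineages fell, on days when many genes did. Of all 18417 genes, 6063, 2721, 4066 and 4600 were lower on days 3, 7, 14 and 21. The median log2 change over all genes was -0.166, -0.095, -0.111 and -0.114. Most members of the oligodendrocyte, endothelium, macrophage and monoamine lists lay below the median level, so their counts alone do not show a loss of lineage markers. NKX2-2, a transcription factor of oligodendrocyte precursors and a Hedgehog target, fell from 8.76 ± 0.35 to 7.18 ± 0.21 by day 21 and MYRF, which drives myelin genes, from 8.92 ± 0.16 to 8.00 ± 0.25 (n = 3). Of 17 oligodendrocyte genes, 12, 3, 8 and 6 were lower on days 3, 7, 14 and 21 (13, 2, 8 and 6 adjusted over the list alone) and 0 higher, and 13 lay below the median level of all genes. For this list the camera adjusted p was 0.034, 0.034, 0.0257 and 0.0467, with adjusted p = 0.731, 0.731, 0.723 and 0.731 with an estimated correlation. The call was lost without day 0 replicate 3 on days 3, 7 and 21 (0.0512, 0.058 and 0.0899), and on day 21 also without day 21 replicate 1 (0.068) or replicate 3 (0.0809). Quantile normalization applied again gave 0.0699 on day 3 and 0.0596 on day 21, and centring 0.0531 on day 21. With dim genes left out none of the 4 days was called (0.331, 0.287, 0.331 and 0.211). CDH5, the cadherin of endothelium, fell from 8.51 ± 0.43 to 7.00 ± 0.16 by day 14 (n = 3). Of 12 endothelium genes, 11 of them below the median level, 6 and 7 were lower on days 7 and 14 (6 and 7 adjusted over the list alone) and 0 higher. Their camera adjusted p was 0.0347 and 0.0455, with adjusted p = 0.587 and 0.599 with an estimated correlation. Without day 0 replicate 3 these were 0.0526 and 0.0667, without day 7 replicate 3 0.0521 and without day 14 replicate 3 0.0587. After quantile normalization was applied again they were 0.0553 and 0.0756, with centring 0.0553 and 0.069, and with dim genes left out 0.319 and 0.405.

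Of 12 macrophage and microglia genes, 10 of them below the median level, 7, 4 and 6 were lower on days 3, 7 and 14 (7, 5 and 6 adjusted over the list alone) and 0 higher. CD68, a lysosomal protein, was at 8.24 ± 0.03 on day 14 against 9.13 ± 0.07 (n = 3). In camera, the adjusted p was 0.0453, 0.0426 and 0.036, with adjusted p = 0.731 on each day with an estimated correlation. Without day 0 replicate 3 it was 0.0899, 0.11 and 0.0899, without day 3 replicate 1 0.073, without day 7 replicate 3 0.0576 and without day 14 replicate 3 0.0883. With the replicate block the day 3 value was 0.0582. Quantile normalization applied again gave 0.0873, 0.0697 and 0.0679, and centring 0.0597, 0.0589 and 0.0518. Leaving out dim genes gave 0.195, 0.0853 and 0.0846. CHRNB2, a nicotinic receptor subunit, fell from 11.08 ± 0.17 to 9.84 ± 0.08 by day 3, when 14 of 22 monoamine and acetylcholine genes were lower and 0 higher (15 and 1 adjusted over the list alone). The camera adjusted p of that list was 0.0169 on day 3 and 0.0455 on day 14, when 7 members were lower (1 adjusted over the list alone) and 0 higher. With an estimated correlation, the adjusted p = 0.743 and 0.796. Of the 22 members 20 lay below the median level, and with dim genes left out neither day was called (0.759 and 0.592). The day 14 call was lost without day 0 replicate 3 (0.0899) or day 14 replicate 3 (0.173), after quantile normalization was applied again (0.0612) and with centring (0.0589).

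Proneural, glutamate, GABA, channel and radial glia lists held single genes with large changes, and none of these lists was called on any day in the reported fit. ATOH1, a proneural factor of the dorsal hindbrain, rose from 7.94 ± 0.06 to 11.15 ± 1.08 by day 14 (n = 3, adjusted p = 2.06e-05). DLX2, a factor of ventral forebrain interneurons, rose from 7.95 ± 0.15 to 10.78 ± 0.16 on day 1. Of 23 proneural and neuronal transcription factors, 5 were higher and 1 lower on day 21 (5 and 1 adjusted over the list alone), and the smallest camera adjusted p over the days was 0.368, on day 3 (adjusted p = 0.836 with an estimated correlation). GRIK1, a kainate receptor subunit, rose from 5.81 ± 0.18 to 9.19 ± 0.79 by day 21. Of 22 glutamate genes, 9 were higher and 3 lower on that day (9 and 5 adjusted over the list alone), with a median of -0.10, a mean of 0.28 and a camera adjusted p of 0.264 (adjusted p = 0.796 with an estimated correlation). With the length trend removed the glutamate list was called lower on day 1 (adjusted p = 0.0294). ABAT, which breaks down GABA, rose from 10.36 ± 0.28 to 11.33 ± 0.22 and SLC32A1, which loads GABA into vesicles, fell from 7.65 ± 0.07 to 7.26 ± 0.11. Of 15 GABA genes, 1 was higher and 3 lower on day 21 (1 and 3 adjusted over the list alone), and the smallest camera adjusted p was 0.184, on day 3 (adjusted p = 0.806 with an estimated correlation). With the length trend removed the GABA list was called lower on day 1 (adjusted p = 0.042) and day 3 (0.0156). KCND2, a potassium channel, rose from 5.86 ± 0.17 to 7.39 ± 0.49. Of 20 channel genes, 4 were higher and 4 lower on day 21 (4 and 4 adjusted over the list alone; camera adjusted p = 0.362, adjusted p = 0.796 with an estimated correlation). TNC, a matrix protein of radial glia, rose from 8.80 ± 0.52 to 11.60 ± 0.53. Of 18 radial glia genes, 8 were higher and 3 lower on day 21 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0592, adjusted p = 0.274 with an estimated correlation, 0.048 after quantile normalization was applied again, 0.0443 without day 0 replicate 1).

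Across the 170 list tests, 57 were called with the preset correlation, and 0 were called with an estimated correlation. The median, the mean and the test differed in sign in 36 of the 170, of which 0 were called. These lay in the lists for DNA replication, proneural factors, synapse, glutamate, channels, astrocyte, radial glia, neural crest, epithelium, forebrain, Notch, Wnt, Hedgehog, unfolded protein, interferon and housekeeping genes.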

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

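These settings were chosen after seeing the data: removal of the gene-length trend, the same with the replicate block, leaving out all day 1 arrays, and centring in the list tests. Averaging the rows of a gene, testing each row, the trended robust prior, centring and removal of the length trend left the counts of all 9 comparisons and of the F test within 1.5 times their reported values. With the replicate block the counts were 158 for day 7 against day 3, 285 for day 14 against day 7 and 328 for day 21 against day 14. With the number as a random effect (consensus correlation 0.074) they were 91, 212 and 287, and with the length trend removed and the replicate block 171, 346 and 397. Fits of only the 6 arrays compared, which have fewer residual degrees of freedom, gave 600 for day 3 against day 1, 13 for day 14 against day 7 and 0 for day 21 against day 14 (2077 at an unadjusted p under 0.05 in the fit of 18 arrays). The same fits gave 10824 genes for day 3 and 7527 for day 7 against day 0, more than the reported 9618 and 5453. Fewer degrees of freedom would not raise these 2 counts, but may have a part in the losses. Spread also differed by day. The SD over genes of the difference within a pair of arrays was at most 0.245, 0.271 and 0.225 on days 0, 3 and 7. It reached 0.471, 0.334 and 0.377 on days 1, 14 and 21, and the fit of 18 arrays pools these spreads. Day 7 against day 3 nonetheless fell from 56 to 41. Quantile normalization applied again gave 115 for day 21 against day 14. Leaving out dim genes, so that fewer genes were tested, gave 5087, 4071 and 4970 for days 3, 14 and 21 against day 0. Array weights gave 11350 for day 1 and 10248 for day 7 against day 0, then 6296, 1804, 1254 and 2158 for the 4 steps in order of time and 15980 for the F test. Array weights also turned the split from mostly higher to mostly lower for day 3 against day 1 (3004 higher, 3292 lower) and day 14 against day 7 (553 and 701). They gave 3866 and 7484 for day 1 against day 0 (34.1% higher), and 4154 and 6094 for day 7 against day 0 (40.5% higher against 50.1%). Without the day 1 arrays, day 7 against day 3 gave 100. For the block, the random effect, the fits of 6 arrays, quantile normalization, array weights and the day 1 arrays, the cause was not tested.

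Leaving out each array in turn gave 3957 to 7225 genes for day 1, 6418 to 9295 for day 3, 3244 to 5151 for day 7, 3861 to 6458 for day 14 and 5394 to 8809 for day 21 against day 0. The lowest counts came without day 1 replicate 1 for day 1 and without day 0 replicate 3 for the others. For the steps it gave 871 to 1332, 17 to 33, 21 to 129 and 20 to 773 in order of time, lowest without day 3 replicate 3, day 3 replicate 2, day 7 replicate 2 and day 14 replicate 2, and highest in the last without day 21 replicate 2. For the F test it gave 7948 to 10819. Of 72 such counts 25 moved by more than 1.5 times, and each such fit held fewer arrays.

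Of the 170 list tests, 57 lost their call with an estimated correlation, 10 with the replicate block, 12 after quantile normalization, 12 with centring, 22 without dim genes and 6 without the length trend. Removing the length trend also gained 13 calls, all lower: synapse on days 1 and 3 (adjusted p = 0.0475 and 0.00714), glutamate on day 1 (0.0294), GABA on days 1 and 3 (0.042 and 0.0156), monoamine on days 1, 7 and 21 (0.0248, 0.0317 and 0.0435), Hedgehog and hypoxia on day 1 (0.0425 and 0.0477), endothelium on day 3 (0.042) and cholesterol on days 14 and 21 (0.0179 and 0.0248). Leaving out dim genes gained 3, pluripotency on day 3 (0.01), DNA replication on day 14 (0.0336) and cholesterol on day 14 (0.0303), all lower, and quantile normalization gained 1, radial glia on day 21 (0.048). The block ended calls of immediate early genes on day 1 (adjusted p = 0.059), macrophage genes on days 7 and 14 (0.0559 and 0.0503), cholesterol genes on day 7 (0.0726), monoamine genes on day 14 (0.0505), endothelium on day 14 (0.0582) and oligodendrocyte genes on day 21 (0.0505), besides those given for day 3, and changed no other list call. Camera tests a list against other genes, whereas fry tests it against no change, so their calls answer different questions: fry called 102 tests and left 5 of camera's 57 uncalled. The radial glia list on day 3 had no camera call to reverse (adjusted p = 0.937, direction up) and was called lower by fry (median -0.14, adjusted p = 0.0485). Over 1020 list tests without an array, 40 lost and 21 gained a call, among the latter radial glia on day 21 and interferon genes on days 1 and 7, the others in lists called on other days. Of the 751 results for named genes, 2 lost their call with the replicate block, 59 in fits of 6 arrays, 63 without the length trend, 13 after quantile normalization and 11 with centring, and 0 reversed. Of 4506 without an array, 497 lost their call. These genes were named largely for large, called changes in the same data, so these rates do not carry over to other genes. No scanner files were analysed here, so signal over background sets no limit that can be stated.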

Other observations

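EDNRB, an endothelin receptor of neural crest and of glia, rose from 6.85 ± 0.08 on day 0 to 9.88 ± 0.56 on day 21, and the neural crest factors PAX3 and SNAI2 from 7.59 ± 0.27 to 9.29 ± 0.32 and from 10.67 ± 0.66 to 12.20 ± 0.09 (mean ± SD of log2, n = 3). Of the 12 neural crest genes 5 were higher and 4 lower on day 21 (5 and 6 adjusted over the list alone), with a median of -0.20, a mean of 0.41 and a camera adjusted p of 0.531 (adjusted p = 0.806 with an estimated correlation). OTX1, a forebrain and midbrain factor, was at 12.46 ± 0.18 on day 7 against 10.33 ± 0.12. Of 15 forebrain factors 2 were higher and 2 lower on day 21 (2 and 1 adjusted over the list alone), and the smallest camera adjusted p was 0.572, on day 7 (adjusted p = 0.937 with an estimated correlation). HOXB2, a hindbrain factor, fell from 8.95 ± 0.13 to 8.03 ± 0.29. Of 11 HOX genes 0 were higher and 2 lower on day 21 (0 and 2 adjusted over the list alone), and the smallest camera adjusted p was 0.121, on day 14 (adjusted p = 0.796 with an estimated correlation).

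HEY1, a Notch target, rose from 7.69 ± 0.20 to 9.91 ± 0.30 on day 1 (n = 3), when 2 of 18 Notch genes were higher and 6 lower (3 and 8 adjusted over the list alone; camera adjusted p = 0.333, adjusted p = 0.836 with an estimated correlation). CDON, a Hedgehog co-receptor, rose from 8.89 ± 0.53 to 11.16 ± 0.48 by day 21 and PTCH1, receptor and target of the pathway, fell from 12.07 ± 0.10 to 10.57 ± 0.48. Of 14 Hedgehog genes 1 was higher and 5 lower on day 1 (1 and 5 adjusted over the list alone), with the smallest camera adjusted p of the list, 0.109 (adjusted p = 0.767 with an estimated correlation, 0.0425 with the length trend removed). IFI44L, an interferon-induced gene, rose from 5.16 ± 0.12 to 7.51 ± 0.97 by day 21 while B2M fell from 10.31 ± 0.07 to 9.24 ± 0.35. Of 16 interferon genes 0 were higher and 7 lower on day 1 (0 and 7 adjusted over the list alone; camera adjusted p = 0.0561, adjusted p = 0.731 with an estimated correlation). That list was called without day 0 replicate 2 on days 1 and 7 (0.0413 and 0.0461), without day 1 replicate 1 (0.0404) and without day 7 replicate 1 (0.0217). KRT18, an epithelial keratin, was at 8.86 ± 0.12 on day 3 against 9.39 ± 0.21, and 9 of 15 epithelium and endoderm genes were lower and 0 higher on that day (9 and 0 adjusted over the list alone; camera adjusted p = 0.115, adjusted p = 0.767 with an estimated correlation). Of 12 housekeeping genes 1 was higher and 7 lower on day 21 (1 and 7 adjusted over the list alone; camera adjusted p = 0.148, adjusted p = 0.599 with an estimated correlation), among them HPRT1, from 9.38 ± 0.16 to 8.44 ± 0.05.

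Among the tests that follow, those of the DNA replication list against mitosis and of the fibroblast transcripts were chosen after the result was seen. The mitosis list rose on day 3 with a median of 1.22, and 3 explanations were weighed. Removing the length trend left a median of 1.302 (1.27 to 1.33 without each array). That trend ran only from -0.237 in the shortest 10% to 0.362 in the longest 10% of brighter genes, too little to make up the median. Removing the slope on the difference between day 1 replicates 1 and 2 left 1.067 (0.948 to 1.19). For the list's median these values argue against either as the whole source. Members differed, though: the median of that difference was 0.0145, but TOP2A stood at 10.23 and 8.47 and KIF11 at 9.92 and 8.36 in replicates 1 and 2. For such members the slope test decides nothing. More cells in every phase was assumed to raise DNA replication genes alike, but their median was 0.178, or 0.109 to 0.187 of the mitosis median without each array. The replication list was still called higher with the preset correlation (camera adjusted p = 0.00318), so this argues only against an equal rise of both lists. The mitosis median also lay above the replication median on days 7, 14 and 21 (0.884 and 0.036, 0.693 and -0.226, 0.114 and -0.872). The gap is thus not particular to day 3. The source of the mitosis rise stays open. A shift of cells toward division is 1 possibility, which may be a biological change with time in culture and was not tested apart from it.

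Day 1 replicates 1 and 2 differed more than any other pair of arrays within a day: the SD over genes of their difference was 0.471, against 0.345 and 0.293 for the other day 1 pairs and 0.188 to 0.377 for pairs within other days. Removing the length trend left 95.3% of it, which argues against that trend. A difference in timing may fit in part, since the difference correlated with the day 3 change (Pearson's r = 0.633, across genes, which are not independent replicates). The same correlation means that the changes from day 0 lie partly along a difference between arrays of 1 day. Component 1, which parted day 0, also spread the day 1 arrays from -11.37 to 34.26. The source of that difference was not found, which limits the reading of the counts against day 0. Of genes at least 2-fold higher by day 3, 94.6% of longer (1139 of 1204) and 75% of shorter ones (132 of 176, exact 95% interval 67.9% to 81.2%) lay further toward day 3 in replicate 1. Of genes at least 2-fold lower, 52.4% of longer (55 of 105, 42.4% to 62.2%) and 61% of shorter ones (64 of 105, 50.9% to 70.3%) did, so timing stays open.

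Mesenchyme genes rose by day 21 with a median of 1.59. Removing the length trend left 1.448 (1.32 to 1.65 without each array). On day 21 that trend ran only from -0.189 in the shortest 10% to 0.386 in the longest 10% of brighter genes. Removing so small a trend could not have taken the median away. The size of the trend, more than its removal, argues against it as the whole source. An outgrowth of general fibroblasts would raise their abundant transcripts, and the median of the 6 of 10 with a day 0 mean under 10 was -0.058, with COL1A1 at 0.97, COL6A2 at 0.42, COL1A2 at 0.13, S100A6 at -0.24, MYL9 at -0.28 and THY1 at -1.97 (4 of the 6 are also on the mesenchyme list). The 4 left out for a higher day 0 mean were SPARC at 0.01, LGALS1 at 0.61, TIMP1 at -0.84 and CAV1 at 0.13. The 6 used went both ways (SD 0.998), so the test decides nothing, and fibroblast outgrowth and a mesenchymal programme in some of the cultured cells stay open.

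Rises of RSPO3, ATOH1 and BMP genes raised the hypothesis of a dorsal midline programme, tested on genes not looked at before and held by no other list. On day 21, 4 of 9 dorsal midline genes were higher and 0 lower (4 and 0 adjusted over the list alone), BMP6 by 2.42, LHX9 by 2.26, WNT2B by 0.84 and LMX1B by 0.70 on the log2 scale, with a median of 0.13 (camera p = 0.0225, 0.222 with an estimated correlation). The other 5 did not pass and went both ways (WNT3A 0.13, LMX1A 0.04, BARHL2 -0.04, BARHL1 -0.13, GDF7 -0.15), and the p under 0.05 rests on the preset correlation, so the programme stays a hypothesis. For choroid plexus genes camera gave p = 0.0977 (0.29 with an estimated correlation), with 4 higher and 1 lower of 11 measured, ENPP2 by 2.17, SLC4A5 by 0.84 and AQP1 by 0.49. The bound set for rejecting it, a p of 0.05 or more, was a wrong choice, since a missed p over members that go both ways (median 0.00) decides nothing.

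Other splits of the same arrays were fitted. The F test gave 10216 genes in the real order and at most 3534 in the others of 100 splits of the 18 arrays. Only 1 of 100, the real one, gave as many, which is the smallest share these draws can reach. The draws treat all arrays as exchangeable, so they argue against chance only under that assumption. The 6 arrays of a comparison make 10 splits, too few for a share under 0.05. A split that mixes the days also puts the day difference into the residual, so low counts there add no support. In 8 of the 9 comparisons 1 split, the real one, gave as many genes. Real and highest other counts were 6371 and 4 for day 1, 9618 and 0 for day 3, 5453 and 0 for day 7, 6867 and 0 for day 14 and 7933 and 0 for day 21 against day 0. They were 1400 and 0, 56 and 0, and 111 and 0 for the first 3 steps. For day 21 against day 14, 2 splits gave as many: the real one gave 173, and the split of day 14 replicates 1 and 2 with day 21 replicate 2 against the other 3 arrays gave 491, which points to a structure of the samples. The replicate block gave 328 genes there. Where the numbers pair the arrays (days 0 and 3, 3 and 7, 14 and 21), the splits that part 3 pairs gave at most 0 other than the real one.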
